A study of Homo sapiens with 12 samples.

How the data were processed

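Messenger RNA from 12 Cal33 xenograft tumour samples was selected with poly-T beads and sequenced in paired 150 bp reads. Per the labels, the authors aligned reads with STAR 2.7.9a to GRCh38 with Gencode 38 gene models and estimated gene counts with RSEM 1.3.1. The deposited values are expected counts per gene, not scaled between libraries; 6.77% to 7.27% of values per library were not whole numbers. The labels state neither the strand setting nor whether reads from the mouse host were separated. Genes whose reads are shared with paralogs, pseudogenes or an overlapping antisense gene, such as histones and mitochondrially encoded genes, carry that uncertainty. The deposit has 1 table per experiment, and both tables list the same 60649 gene IDs. Of these, 60463 had a symbol, 44 were Y copies of pseudoautosomal genes, and 142 had no symbol in the annotation used for names, types and positions (Gencode 44, GRCh38).

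Samples were grouped by their labels into smTEADi, Vehicle, pTEADi and Control, with 3 libraries each. Library totals were 13576494 to 15433679 expected counts, mitochondrially encoded genes took 3.64% to 5.99% and the 10 most abundant genes 10.6% to 15.1%. Within groups, log2 CPM of library pairs correlated at r = 0.968 to 0.983 across genes, and no pair was a duplicate. Replicate numbers were not taken as pairs: the deviations of libraries with the same number from their group means correlated at -0.135 to 0.120 across genes. Across genes, fold changes had Spearman correlations with GC content of 0.033 and 0.053 and with gene length of 0.0019 and -0.0033, for SW-682 and pTEADi in that order.

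Counts were rounded and tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr at its minimum count of 10, libraries were scaled by TMM, and the quasi-likelihood F test was two-sided with a Benjamini-Hochberg adjusted p of 0.05 as the threshold. Each treatment was compared with its own control group, and the difference of the 2 effects was tested in 1 fit of all 12 libraries as (pTEADi minus Control) minus (smTEADi minus Vehicle). The SE of a log2 fold change is its size divided by the square root of F. CPM values of single genes and mean log2 CPM levels of lists are TMM-scaled. Summed CPM of marker and interferon genes, and log2 CPM correlated between library pairs, use the library total without TMM. The biological coefficient of variation was 0.157 in the SW-682 experiment and 0.118 in the pTEADi experiment.

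Before the data were examined, 37 gene lists were fixed from general knowledge, among them markers of host cell types. Lists with at least 5 tested members, 35 in each comparison and 36 for the difference, were tested with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry served as alternatives. A further 7 lists were written after the data had been seen and appear only among the other observations. Their p-values were adjusted over those 7 alone.

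The rule for named genes was fixed before the data were examined. It took the 8 genes that rose most and the 8 that fell most in each comparison among protein-coding genes past the threshold, with at least 5 CPM on average and no overlap between groups. It added up to 4 members of each described list with the smallest p, the TEAD, YAP and TAZ genes with a set of standard targets and growth genes, the genes past the threshold for the difference, and the 6 genes per direction with the largest change in both comparisons. Y-linked genes and XIST were left out.

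Alternatives were RLE and upper-quartile scaling, no low-count filter, a minimum of 10 counts in 3 libraries, DESeq2 1.42.0, limma-voom, unrounded counts, thresholds of 0.01 and of 2-fold, a replicate block, protein-coding genes, leaving out host marker and histone lists, a spread shared by all 4 groups, and leaving out each library. The tests were run on simulated data with known 2-fold and 4-fold changes in 100 genes each. With edgeR, 90%, 95% and 64% of 2-fold changes were recovered for SW-682, pTEADi and the difference, and 100%, 100% and 99% of 4-fold changes. In the same order, 4.52%, 11.4% and 8.43% of calls were false. Changes were placed only in genes of 5 CPM or more, and counts were drawn for each gene independently at its fitted spread. No other gene changed, so these shares are not the power of the tests on the real data. In the real test of the difference, a log2 difference of -3.50 ± 0.73 for the gene CP did not pass (adjusted p = 0.286).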

Results

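Gene expression was measured by sequencing poly-T selected RNA from xenograft tumours of Cal33, a human head and neck squamous cell carcinoma line. TEAD proteins are the DNA-binding partners through which the co-activators YAP and TAZ switch on genes for growth and for the cytoskeleton. The series asks what blocking the YAP/TAZ and TEAD partnership does in this cancer, and it blocked it in 2 ways. In the first comparison, 3 tumour samples treated with the small molecule TEAD inhibitor SW-682 (labelled smTEADi) were set against 3 Vehicle samples. In the second, 3 tumour samples in which doxycycline switched on a TEAD inhibitor named pTEADi were set against 3 Control samples. Each library held 13576494 to 15433679 expected counts, and 14553 to 14891 genes had 10 or more. No library repeated another: within a group, pairs differed by 7.42 to 34 times the variance that counting noise gives (chi-square per degree of freedom). The labels do not say whether the 3 samples of a group came from separate animals, so p-values measure the spread between these samples. Levels are CPM, counts scaled to the size of the library, as mean ± SD over n = 3 libraries, and log2 fold changes are treated over control ± SE. Adjusted p-values for genes are Benjamini-Hochberg values of edgeR's quasi-likelihood test, and those for gene lists come from camera.

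By camera at its preset correlation, SW-682 was followed by lower YAP/TAZ target, cell cycle and interferon-stimulated lists and by a higher squamous differentiation list. None of its 17 list calls passed with an estimated correlation (smallest adjusted p = 0.321) or with fry, a directional test (smallest adjusted p = 0.0625). Of 14829 genes tested, 300 rose and 516 fell. CCN1, a matricellular gene and a standard YAP/TAZ target (ENSG00000142871.18, GRCh38 chromosome 1, 85580761 to 85584589, plus strand), went from 36.1 ± 3.61 CPM with vehicle to 12.5 ± 3.55 CPM, a log2 fold change of -1.52 ± 0.20 (adjusted p = 0.0365). Among protein-coding genes with a mean of 5 CPM or more and no overlap between groups, those that rose most were TMPRSS11B, a transmembrane serine protease of squamous epithelium (ENSG00000185873.8, chromosome 4, 68226653 to 68245694, minus strand; 2.40 ± 0.41), KRT9 (2.40 ± 0.39), PSCA (2.37 ± 0.51), CLCA4 (2.23 ± 0.34), MAL (2.22 ± 0.38), B3GALT5 (2.10 ± 0.41), PRSS27 (1.83 ± 0.40) and FUT6 (1.79 ± 0.40). By the same rule, those that fell most were IL7R, the interleukin 7 receptor (-2.70 ± 0.35), HEPHL1 (-2.02 ± 0.48), the growth factor FGF2 (-2.0 ± 0.28), NT5E (-1.88 ± 0.37), the mesenchymal filament gene VIM (-1.86 ± 0.29), KRT75 (-1.84 ± 0.38), CMPK2 (-1.77 ± 0.37) and the matrix gene THBS1 (-1.76 ± 0.29).

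Among YAP/TAZ target genes, 6 of 20 tested fell and none rose. When adjusted over the list alone, 9 fell and 1 rose. The 6 genes that fell over all genes included, besides CCN1, DOCK5 (-0.72 ± 0.12), TGFB2 (-1.27 ± 0.23) and CRIM1 (-0.56 ± 0.11). The list's median log2 fold change was -0.27 (camera adjusted p = 0.000168; adjusted p = 0.321 with an estimated correlation). CCN2 and ANKRD1, which are often used as readouts, could not be read here: CCN2 had 0 to 9 counts and ANKRD1 0 to 2 counts per library. AMOTL2 (-0.26 ± 0.09, adjusted p = 0.119) and AXL (-1.03 ± 0.34, adjusted p = 0.0931) did not pass. TEAD4 fell (-1.09 ± 0.25), and the remaining genes of the complex did not pass: YAP1 (0.29 ± 0.11), WWTR1, which encodes TAZ (-0.12 ± 0.16), TEAD1 (-0.12 ± 0.12), TEAD2 (-0.35 ± 0.11) and TEAD3 (0.42 ± 0.14). Of 24 Hippo pathway components, TEAD4 and MAP4K4 fell (-0.38 ± 0.09) and none rose. When adjusted over the list alone, 2 fell and 1 rose (camera adjusted p = 0.979).

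Cell cycle genes formed the group with most calls. Of 54 G2/M genes 41 fell, among them AURKB (-1.34 ± 0.19), KIF23 (-1.24 ± 0.18), CKAP2L (-1.53 ± 0.24) and UBE2C (-1.51 ± 0.24). A total of 50 fell adjusted over the list alone (camera adjusted p = 6.33e-41; adjusted p = 0.321 with an estimated correlation). Of 43 S phase genes 19 fell, including TYMS (-1.34 ± 0.24), RRM2 (-1.56 ± 0.30), MCM7 (-0.80 ± 0.15) and ATAD2 (-0.94 ± 0.19). A total of 38 fell adjusted over the list alone (camera adjusted p = 9.15e-24; adjusted p = 0.344 with an estimated correlation). Of 18 cyclin-dependent kinase inhibitor and quiescence genes, TXNIP (1.0 ± 0.22), CDKN2B (0.64 ± 0.15) and CDKN1A, which encodes p21 (0.62 ± 0.15), rose and none fell. When adjusted over the list alone, 4 rose and 1 fell (camera adjusted p = 0.00442; adjusted p = 0.392 with an estimated correlation). MYC itself (-0.22 ± 0.10, adjusted p = 0.211), CCND1 (-0.08 ± 0.17, adjusted p = 0.799) and EGFR (-0.23 ± 0.11, adjusted p = 0.206) did not pass. Of 28 MYC and ribosome biogenesis genes, TCOF1 (-0.81 ± 0.16) and NOP56 (-0.73 ± 0.17) fell. A total of 18 fell adjusted over the list alone (camera adjusted p = 1.59e-10; adjusted p = 0.392 with an estimated correlation). Of 11 histone genes, 4 rose, namely H2AC6 (1.02 ± 0.15), H2BC21 (1.04 ± 0.21), H3C10 (1.21 ± 0.25) and H1-2 (0.82 ± 0.20). A total of 6 rose adjusted over the list alone (camera adjusted p = 3.6e-06; adjusted p = 0.321 with an estimated correlation). The median of the histone list was 0.82, or 0.512 without smTEADi 1. Histone messages of this kind mostly lack the poly-A tail by which these libraries were selected.

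Of 31 interferon-stimulated genes 20 fell and none rose. A total of 29 fell adjusted over the list alone. The median log2 fold change was -1.03 (camera adjusted p = 2.32e-27; adjusted p = 0.321 with an estimated correlation). OASL (-1.66 ± 0.20), the ubiquitin-like gene ISG15 (-1.54 ± 0.25), IFIT3 (-1.55 ± 0.25) and IFITM3 (-1.17 ± 0.19) had the smallest p-values. Of 16 antigen presentation genes 5 fell, including the peptide transporter gene TAP1 (-0.67 ± 0.14). A total of 15 fell adjusted over the list alone (camera adjusted p = 2.27e-09; adjusted p = 0.344 with an estimated correlation). Of 14 NF-kB cytokine and chemokine genes, CCL5 (-1.5 ± 0.31) and CXCL1 (-2.68 ± 0.58) fell. A total of 4 fell adjusted over the list alone (camera adjusted p = 0.00198; adjusted p = 0.321 with an estimated correlation). Markers of macrophages and leukocytes summed to 44.5 ± 4.5 CPM with vehicle and 48.7 ± 13 CPM with SW-682, and their median log2 fold change was 0.02.

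Squamous differentiation genes were higher, with a median log2 fold change of 0.92 over 37 members. Of these, 4 rose, namely KRT4 (1.23 ± 0.22), SPRR3, a cornified envelope gene (1.41 ± 0.33), KRT13 (0.91 ± 0.22) and MAL, and 22 members rose and 1 fell adjusted over the list alone (camera adjusted p = 2.1e-12; adjusted p = 0.392 with an estimated correlation). The libraries of the 2 groups overlapped on this list: Vehicle 2 had a mean log2 CPM of 8.27, above smTEADi 3 at 8.0, while Vehicle 1 and 3 had 6.96 and 7.21. Adipocyte markers were higher as well, summing to 71.4 to 93.99 CPM in the Vehicle libraries and 155.9 to 165.7 CPM in the SW-682 libraries. Of 4 tested, 1 rose, and 2 rose and 1 fell adjusted over the list alone. Partial epithelial-mesenchymal transition genes went the other way, with 14 of 30 lower, none higher, and 19 lower and 2 higher adjusted over the list alone; VIM, THBS1, INHBA (-0.79 ± 0.13) and MT2A (-1.31 ± 0.24) led them (camera adjusted p = 4.9e-12; adjusted p = 0.321 with an estimated correlation). Of 21 basal keratinocyte and hemidesmosome genes 3 fell, among them CDH3 (-0.67 ± 0.13) and LAMA3 (-0.58 ± 0.13). A total of 8 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000191; adjusted p = 0.392 with an estimated correlation). Of 27 actin and focal adhesion genes 7 fell, among them ARHGAP29 (-0.85 ± 0.14), ANLN (-1.5 ± 0.25) and the adhesion adaptor PXN (-0.65 ± 0.12). A total of 13 fell adjusted over the list alone (camera adjusted p = 8.06e-07; adjusted p = 0.321 with an estimated correlation). Of 21 TGF-beta response genes 5 fell, including the basement membrane collagens COL4A1 (-0.88 ± 0.17) and COL4A2 (-0.96 ± 0.18). A total of 8 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000443; adjusted p = 0.321 with an estimated correlation). Fibroblast and collagen genes, listed as markers of host stroma, were also lower by list (camera adjusted p = 0.0428, or 0.344 with an estimated correlation). Fold changes were negative in 9 of 11. FN1 alone passed the threshold (-1.36 ± 0.30), over all genes as adjusted over the list alone. These markers summed to 772 ± 33.8 CPM with vehicle and 686 ± 64.6 CPM with SW-682. The list call was lost without smTEADi 1 (camera adjusted p = 0.0607) and Vehicle 2 (camera adjusted p = 0.129). Whether these reads came from host or tumour cells is not known.

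Few energy genes passed with SW-682. Of 34 nuclear oxidative phosphorylation genes SDHA fell (-0.70 ± 0.09), at a list median of -0.195, or -0.091 without smTEADi 1. A total of 1 fell adjusted over the list alone (camera adjusted p = 0.000351; adjusted p = 0.595 with an estimated correlation). None of 30 cytosolic ribosomal protein genes passed, nor did any adjusted over the list alone, at a median of -0.18, or -0.10 without smTEADi 1 (camera adjusted p = 0.000892; adjusted p = 0.676 with an estimated correlation). Hypoxia genes (median 0.17, camera adjusted p = 0.650) and glycolysis genes (median -0.07, camera adjusted p = 0.222) did not pass as lists, and of both lists PLOD2 alone fell (-0.86 ± 0.15). Adjusted over the list alone, 1 hypoxia gene rose and 1 fell, and 0 glycolysis genes passed. The SW-682 libraries parted on the hypoxia list, at mean log2 CPM of 7.12, 6.82 and 5.81 against 6.41 to 6.74 with vehicle. Its median was -0.07 without smTEADi 1 and 0.40 without smTEADi 3. The ligand gene NRG1 fell (-1.54 ± 0.26) and the receptor gene ERBB2 rose (0.63 ± 0.16), while the list of EGFR family and ligands did not pass (camera adjusted p = 0.606); 5 of its 14 genes rose and 2 fell adjusted over the list alone.

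The SW-682 calls sat close to the threshold. The smallest adjusted p was 0.0365, and although 4128 genes had an unadjusted p under 0.05, none passed an adjusted p of 0.01. The count of 816 became 0 without smTEADi 3, Vehicle 1 or Vehicle 3, 335 without smTEADi 1, 402 without smTEADi 2 and 1622 without Vehicle 2, and the 6 YAP/TAZ targets likewise became 0 without smTEADi 3, Vehicle 1 or Vehicle 3; DESeq2 called 1893 genes. On the first principal component smTEADi 1 lay at 58.0, away from smTEADi 2 and 3 at 15.8 and 10.5, and Vehicle 2 lay at -7.24, away from Vehicle 1 and 3 at -35.0 and -42.1. All 816 called genes kept their sign in each fit without 1 library. In all 816 the CPM of the groups did not overlap, as in 33% of all genes tested, where chance gives 10%.

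By camera, pTEADi was followed by lower interferon-stimulated, cell cycle, YAP/TAZ target, hypoxia and glycolysis lists and by a higher squamous differentiation list. None of its 19 list calls passed with an estimated correlation (smallest adjusted p = 0.077), and fry called 16 of them. Of 14705 genes tested, 1866 rose and 1998 fell, and 2138 passed an adjusted p of 0.01. CCN1 went from 63.5 ± 17.1 CPM in Control to 23.7 ± 6.76 CPM, a log2 fold change of -1.42 ± 0.21 (adjusted p = 0.000624). Under the same rule of 5 CPM or more, the largest rise was that of CES1, a carboxylesterase gene (ENSG00000198848.13, GRCh38 chromosome 16, 55802851 to 55833337, minus strand), from 1.59 ± 0.843 to 30.7 ± 3.6 CPM (4.26 ± 0.26). Next came GSDMA (3.21 ± 0.38), the filaggrin genes FLG2 (2.93 ± 0.43) and FLG (2.93 ± 0.44), TMPRSS11B (2.93 ± 0.47), LORICRIN, a main protein of the cornified envelope (2.91 ± 0.44), RPTN (2.72 ± 0.20) and the transcription factor ELF5 (2.65 ± 0.34). The largest fall under that rule was that of IL7R (ENSG00000168685.15, chromosome 5, 35852695 to 35879603, plus strand), from 25.3 ± 15.5 to 0.813 ± 0.0766 CPM (-4.94 ± 0.48). It was followed, again at 5 CPM or more, by the interferon-induced RSAD2 (-4.36 ± 0.51), CP (-4.16 ± 0.35), CMPK2 (-3.34 ± 0.47), FN1 (-3.29 ± 0.38), FGF2 (-3.23 ± 0.34), IFI44L (-3.15 ± 0.32) and the cytokine gene IL1B (-3.03 ± 0.44).

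Of 21 YAP/TAZ target genes tested 14 fell and none rose, with 15 lower adjusted over the list alone. DOCK5 (-0.93 ± 0.11), F3 (-1.37 ± 0.19) and NT5E (-2.23 ± 0.32) led them with CCN1, and the median was -0.58 (camera adjusted p = 9.01e-07; adjusted p = 0.077 with an estimated correlation). AMOTL2 (-0.50 ± 0.10, adjusted p = 0.00369), AXL (-1.55 ± 0.37, adjusted p = 0.00965) and CCN2 (-2.02 ± 0.59, adjusted p = 0.0259) fell as well, CCN2 from only 11 to 31 counts per Control library; ANKRD1 had at most 1 count per library. WWTR1 (-0.57 ± 0.10), TEAD4 (-0.71 ± 0.17) and TEAD2 (-0.36 ± 0.11) fell, whereas YAP1 (-0.07 ± 0.10), TEAD1 (0.06 ± 0.10) and TEAD3 (0.25 ± 0.09) did not pass. Of 24 Hippo pathway components 5 fell and none rose, with the same counts adjusted over the list alone (camera adjusted p = 0.289). The target count ranged from 8 to 13 when single libraries were left out, and was 9 without pTEADi 1 and 8 without pTEADi 3.

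Every one of the 31 interferon-stimulated genes fell, and all 31 fell adjusted over the list alone. The median was -1.35 (camera adjusted p = 5.51e-49; adjusted p = 0.077 with an estimated correlation), with IFI6 (-2.19 ± 0.10), OAS3 (-1.15 ± 0.08), the antiviral GTPase gene MX1 (-1.35 ± 0.10) and IFIT3 (-2.80 ± 0.21) at the smallest p-values. Of 16 antigen presentation genes 13 fell, including the immunoproteasome gene PSMB9 (-1.14 ± 0.11), TAP1 (-0.74 ± 0.10), TAP2 (-0.67 ± 0.08) and HLA-B (-0.99 ± 0.14). A total of 15 fell adjusted over the list alone (camera adjusted p = 2.67e-11; adjusted p = 0.196 with an estimated correlation). Of 15 NF-kB cytokine and chemokine genes 12 fell, the same number adjusted over the list alone, with CCL5 (-2.55 ± 0.26), CXCL1 (-3.78 ± 0.55) and IL1A (-1.97 ± 0.38) beside IL1B (camera adjusted p = 2e-07; adjusted p = 0.366 with an estimated correlation). Control 2 stood apart on this list, at a mean log2 CPM of 4.23 against 3.26 and 2.76 in Control 1 and 3, and the median of -1.71 was -1.06 without it. Leukocyte markers were lower too, summing to 62.6 ± 15 CPM in Control and 40.5 ± 4.4 CPM with pTEADi; of 6 tested, CD74 (-0.59 ± 0.11) and CSF1R (-1.39 ± 0.41) fell, 3 fell adjusted over the list alone, and the list did not pass (camera adjusted p = 0.286).

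With pTEADi, of 54 G2/M genes 48 fell and 50 did so adjusted over the list alone, among them ANLN (-1.38 ± 0.08), KIF23 (-1.12 ± 0.09), UBE2C (-1.08 ± 0.10) and the spindle motor gene KIF11 (-1.05 ± 0.10) (camera adjusted p = 4.6e-46; adjusted p = 0.085 with an estimated correlation). Of 43 S phase genes 34 fell and 37 did so adjusted over the list alone, with CDCA7 (-1.69 ± 0.14), RRM2 (-0.98 ± 0.10), UHRF1 (-0.99 ± 0.11) and MCM4 (-0.71 ± 0.08) first (camera adjusted p = 2.03e-21; adjusted p = 0.196 with an estimated correlation). MYC fell (-0.72 ± 0.13), and 19 of 28 MYC and ribosome biogenesis genes fell, 20 adjusted over the list alone (camera adjusted p = 2.7e-09; adjusted p = 0.349 with an estimated correlation). Of 30 cytosolic ribosomal protein genes 4 fell, led by RPS3 (-0.42 ± 0.11), and none passed adjusted over the list alone (camera adjusted p = 0.00295; adjusted p = 0.648 with an estimated correlation). The median of the ribosomal protein list was -0.216, or -0.138 without Control 2 and -0.335 without Control 3. Unlike MYC, CCND1 rose (0.44 ± 0.09), and EGFR did not pass (-0.23 ± 0.10). TXNIP (1.71 ± 0.09), CDKN1A (0.83 ± 0.10) and the antiproliferative BTG2 (1.08 ± 0.15) were among 6 of 18 kinase inhibitor and quiescence genes that rose, while KLF6 fell (-0.66 ± 0.13), with the same counts adjusted over the list alone (camera adjusted p = 0.000651; adjusted p = 0.125 with an estimated correlation). Of 12 histone genes 5 rose and none fell. A total of 7 rose adjusted over the list alone (camera adjusted p = 0.00224; adjusted p = 0.349 with an estimated correlation).

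Of 37 squamous differentiation genes 26 rose and 1 fell. A total of 28 rose and 2 fell adjusted over the list alone. The exception that fell was the protease gene KLK5, named here after its values were seen. S100A7 rose from 213 ± 20.9 to 875 ± 58.0 CPM (2.04 ± 0.10), and CALML5 (2.38 ± 0.14), DMKN (1.21 ± 0.10) and SBSN (1.19 ± 0.11) followed (camera adjusted p = 5.6e-21; adjusted p = 0.077 with an estimated correlation). Of 30 partial epithelial-mesenchymal transition genes 17 fell, with THBS1 (-1.69 ± 0.18) and FSTL3 (-0.90 ± 0.11), and 3 rose, with MMP10 first (1.57 ± 0.11). The counts were the same adjusted over the list alone (camera adjusted p = 2.02e-05; adjusted p = 0.349 with an estimated correlation). Of 27 actin and focal adhesion genes 12 fell and 1 rose. A total of 17 fell and 1 rose adjusted over the list alone, with ARHGAP29 (-1.04 ± 0.12), PXN (-0.91 ± 0.11) and ACTN1 (-0.72 ± 0.10) after ANLN (camera adjusted p = 1.52e-07; adjusted p = 0.196 with an estimated correlation). Of 21 TGF-beta response genes 10 fell and none rose, as adjusted over the list alone, with COL4A1 (-1.09 ± 0.09) and COL4A2 (-1.02 ± 0.10) (camera adjusted p = 6.46e-06; adjusted p = 0.077 with an estimated correlation). Fibroblast markers summed to 817 ± 75.5 CPM in Control and 609 ± 20.6 CPM with pTEADi, and 4 of 11 tested fell, led by FN1, with the same count adjusted over the list alone (camera adjusted p = 0.0504). Adipocyte markers summed to 58.46 to 67.16 CPM in the Control libraries and 104 to 111.2 CPM with pTEADi.

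With pTEADi, 13 of 22 hypoxia genes fell and 1 rose. A total of 15 fell and 1 rose adjusted over the list alone, among them the carbonic anhydrase gene CA9 (-2.65 ± 0.18), the collagen-modifying enzyme genes PLOD2 (-1.34 ± 0.09) and P4HA1 (-1.13 ± 0.10), and BNIP3 (-0.95 ± 0.13) (median -0.91, camera adjusted p = 1.28e-09; adjusted p = 0.196 with an estimated correlation). Of 19 glycolysis genes 14 fell and 16 did so adjusted over the list alone, with ENO2 (-2.26 ± 0.22), PFKFB3 (-1.22 ± 0.16) and GPI (-0.71 ± 0.10) (camera adjusted p = 2.17e-08; adjusted p = 0.366 with an estimated correlation). Of 25 genes of the ATF4 and mitochondrial stress response 14 fell and 2 rose. A total of 15 fell and 2 rose adjusted over the list alone, with MTHFD2 (-1.35 ± 0.13), DDIT4 (-1.74 ± 0.17), SLC7A5 (-0.94 ± 0.10) and STC2 (-2.28 ± 0.40) (camera adjusted p = 6.8e-06; adjusted p = 0.349 with an estimated correlation). Of 16 unfolded protein response genes 7 fell, PDIA4 first (-0.62 ± 0.08), and 2 rose, as adjusted over the list alone (camera adjusted p = 0.0263; adjusted p = 0.448 with an estimated correlation); the call was lost without Control 2, pTEADi 2 or pTEADi 3, at adjusted p = 0.0534, 0.0515 and 0.0559. Of 13 mitochondrially encoded genes 6 rose, as adjusted over the list alone, with MT-CYB at 0.62 ± 0.12 and MT-ND6 at 0.63 ± 0.13 (camera adjusted p = 0.0124; adjusted p = 0.580 with an estimated correlation), and the list call was lost without Control 2 (adjusted p = 0.0946). Doxycycline was given to the pTEADi group and not to the Control group, so the inhibitor and the inducer cannot be separated in this comparison.

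The 3864 calls with pTEADi became 2573 without Control 1 and 2325 without pTEADi 2, with 2513 and 2293 of the 3864 among them. In 3795 of the called genes the CPM of the groups did not overlap, as in 42% of all genes tested, where chance gives 10%. The fry test called 19 of 35 lists with pTEADi, 16 of them called by camera, and none with SW-682 (smallest adjusted p = 0.0625), where 2 lists had a camera p under 0.05 with an estimated correlation; with pTEADi, 8 lists did and none passed after adjustment.

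**Figure D1:**
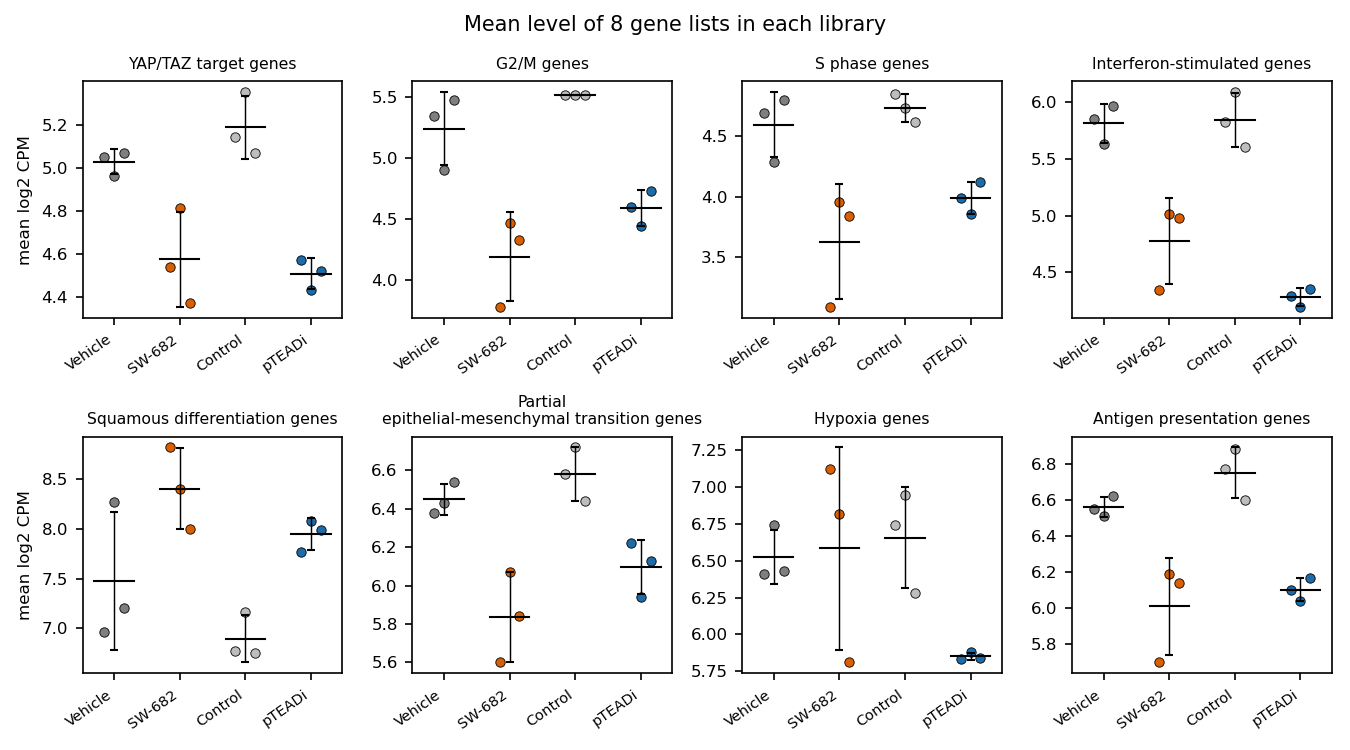
Mean log2 CPM of 8 gene lists in each of the 12 libraries, all scaled together. Each point is a library, and bars give the mean and SD of the 3 libraries of a group; the G2/M and interferon-stimulated lists are lower in every treated library than in every library of its control group, while on the squamous differentiation list Vehicle 2 (8.27) lies within the SW-682 libraries (8.0 to 8.82).

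**Figure D2:**
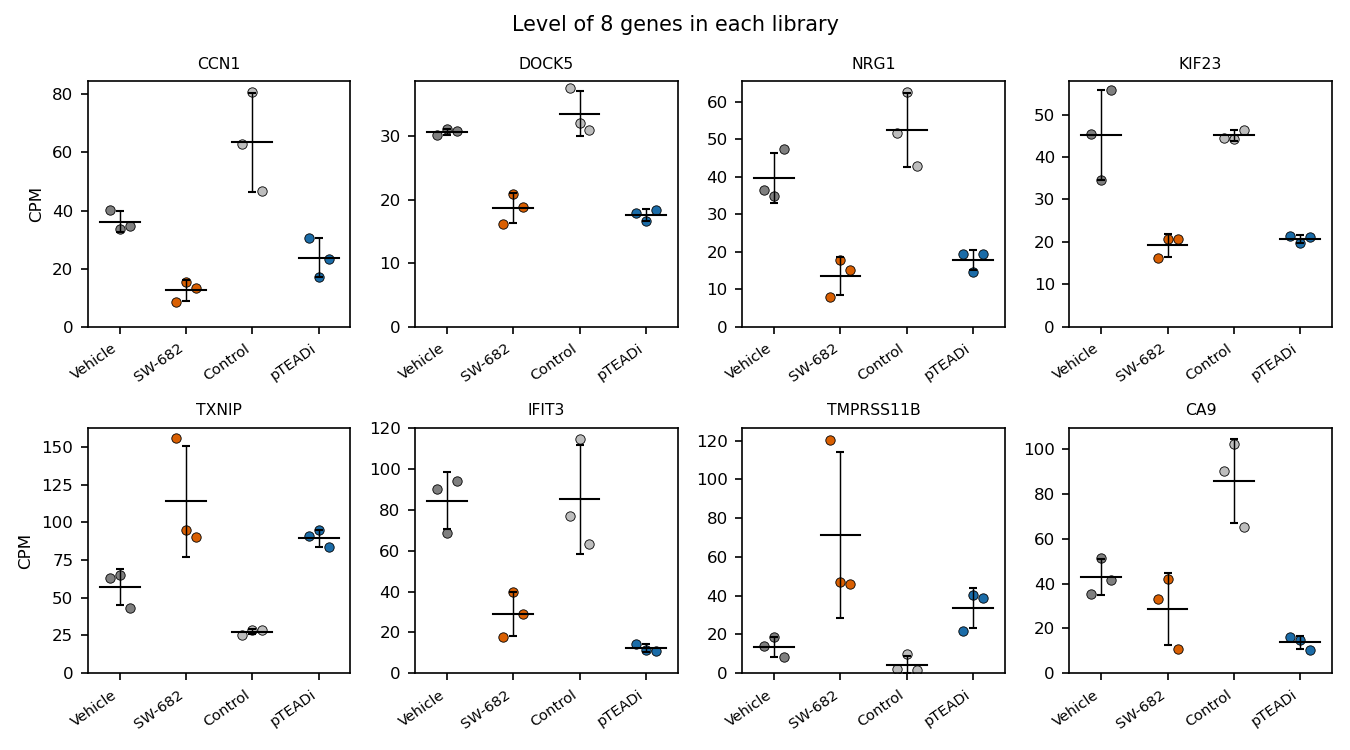
CPM of 8 named genes in each library, on axes that start at 0. Points are libraries, and bars give the mean and SD of the 3 libraries of a group; CCN1 goes from 36.1 to 12.5 CPM with SW-682 and from 63.5 to 23.7 CPM with pTEADi, and CA9 has a log2 fold change of -2.65 with pTEADi.

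The 2 inhibitors were then compared with each other, since both are meant to act on TEAD. They share no control libraries. Among called genes with 5 CPM or more in both comparisons, those that moved most in both were, upward, TMPRSS11B, CLCA4, MAL, B3GALT5, FUT6 and FAM3D (1.77 ± 0.36 with SW-682 and 2.40 ± 0.43 with pTEADi) and, downward, IL7R, FGF2, NT5E, VIM, KRT75 and CMPK2. Across 14384 genes tested in both, fold changes correlated with Pearson r = 0.675 and Spearman rho = 0.671; genes are not independent replicates. In the same direction, 257 genes rose in both, where independent lists would share 38.4, and 470 fell in both, where 70.5 would be shared. Of 813 SW-682 calls 99.5% had the same sign with pTEADi, and of 3821 pTEADi calls 94.8% had the same sign with SW-682. The shared count of 727 followed the SW-682 calls, falling to 0 without smTEADi 3, Vehicle 1 or Vehicle 3, to 314 without smTEADi 1 and to 372 without smTEADi 2, and rising to 1331 without Vehicle 2.

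**Figure D3:**
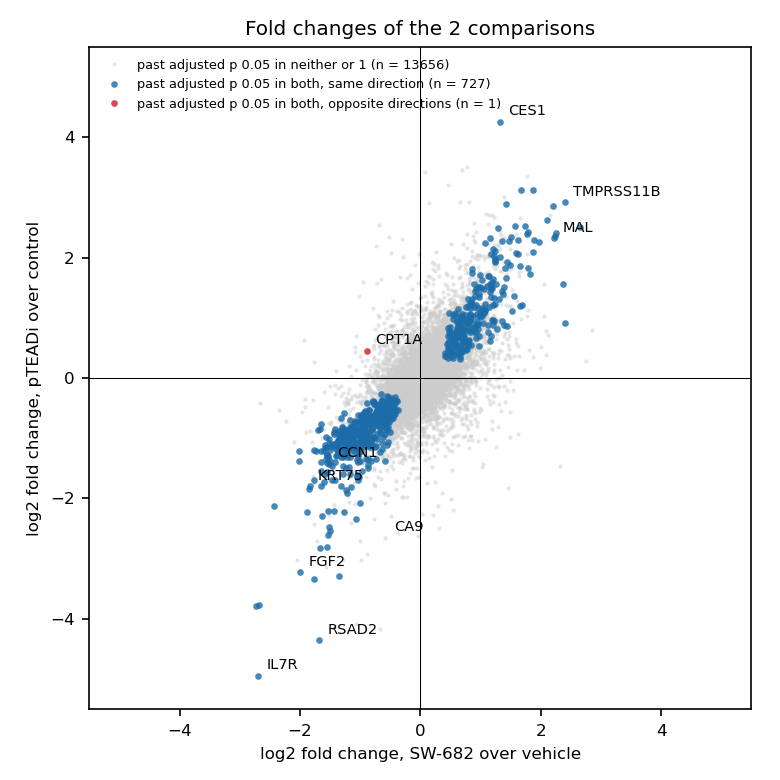
Log2 fold change with pTEADi against that with SW-682 for 14384 genes. Blue points are the 727 genes past an adjusted p of 0.05 in both with the same sign, the red point is CPT1A, past the threshold with opposite signs, grey points are all others, and 1 gene lies outside the axes.

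The test of the difference itself passed for 2 of 15460 genes, both higher with pTEADi relative to SW-682. CPT1A, which encodes the rate-limiting enzyme of mitochondrial fatty acid import (ENSG00000110090.13, chromosome 11, 68754620 to 68844410, minus strand), fell with SW-682 (-0.88 ± 0.13) and rose with pTEADi (0.46 ± 0.13), a difference of 1.34 ± 0.18 (adjusted p = 0.0451). CEMIP, a hyaluronan-degrading gene (ENSG00000103888.17, chromosome 15, 80779343 to 80951776, plus strand), rose with pTEADi (1.34 ± 0.11) and not with SW-682 (0.01 ± 0.16), a difference of 1.33 ± 0.19 (adjusted p = 0.0451). CES1, at 1.33 ± 0.31 with SW-682, differed by 2.94 ± 0.47 without passing (adjusted p = 0.0815). CCN1 differed by 0.10 ± 0.33 (adjusted p = 0.976). The count of 2 became 0 without Control 1, Control 3, smTEADi 2, Vehicle 1, Vehicle 3 or any pTEADi library, 1 without Control 2, 3 without smTEADi 1 and 20 without smTEADi 3; it was 43 with DESeq2, and 1103 genes had an unadjusted p under 0.05. Upper-quartile scaling gave 2 genes higher and 1 lower in place of 2 higher.

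By list, 16 of 36 passed the test of the difference with camera, and none with an estimated correlation, where 3 had an unadjusted p under 0.05. Hypoxia genes had the smallest camera p of these, and were lower with pTEADi by a median of -1.04 on the log2 scale (camera adjusted p = 7.91e-15; adjusted p = 0.339 with an estimated correlation), with 13 of 22 lower adjusted over the list alone and none over all genes. Interferon-stimulated genes differed by -0.44 (camera adjusted p = 7.54e-11; adjusted p = 0.339 with an estimated correlation), with 3 of 31 lower adjusted over the list alone and none over all genes. YAP/TAZ target genes differed by -0.24, with none of 21 past the threshold by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.0385; adjusted p = 0.339 with an estimated correlation), and that call was lost without Control 2, pTEADi 2, pTEADi 3, smTEADi 2 or Vehicle 2, at adjusted p = 0.147, 0.0795, 0.0634, 0.335 and 0.0975. The median was -0.07 without Control 2 and -0.04 without smTEADi 2.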

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

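The tests of single libraries (medians included), host leukocytes, doxycycline stress, control levels, spread and effect size were chosen only after the results were seen. The counts over other splits of the libraries were planned, but not their breakdown by which real grouping a split kept.

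A test of the difference between the 2 treatments' effects singled out 2 genes, CPT1A at 1.34 and CEMIP at 1.33 on the log2 scale. Of 100 drawn splits of the 12 libraries, 8 gave as many genes, the real one included, but all 8 kept the real pTEADi grouping and so carry its effect, which leaves chance undecided for that count. The highest other split gave 5436 genes; it kept both real groupings and turned 1 round, which adds the effects, a structure of the samples. By the planned rule, which counted all drawn splits, 8 of 100 did not exclude chance. Of the 73 splits that kept neither real grouping, 0 gave as many (highest 1). Those splits mix treated and control libraries in each group. Mixed so, neither experiment alone called more than 1 gene, so that result decides nothing. For the 16 lists that differed, 39 of the 100 splits gave as many (highest other 23), as did 15 of those 73 (highest 22), and chance is not excluded.

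Besides hypoxia genes (-1.04), lists with a lower effect of pTEADi were NF-kB cytokines and chemokines (-1.10), interferon-stimulated genes (-0.44), ATF4 and mitochondrial stress genes (-0.44), glycolysis genes (-0.41), AP-1 and immediate early genes (-0.29), YAP/TAZ target genes (-0.24), apoptosis regulators (-0.18) and cholesterol synthesis genes (-0.18), as median log2 differences. Lists with a higher effect were mitochondrially encoded genes (0.33), heat shock genes (0.31), NRF2 target genes (0.20), S phase genes (0.19), basal keratinocyte genes (0.17), nuclear oxidative phosphorylation genes (0.15) and partial epithelial-mesenchymal transition genes (0.11). Lower means more negative and higher more positive, not weaker or stronger. For S phase genes, medians were negative with both treatments, less so with pTEADi (-0.938 with SW-682 and -0.724 with pTEADi). The same held for basal keratinocyte (-0.30 and -0.11), nuclear oxidative phosphorylation (-0.195 and -0.041) and partial epithelial-mesenchymal transition genes (-0.646 and -0.474). Medians of the other higher lists were negative with SW-682 and positive with pTEADi. With an estimated correlation, adjusted p was 0.339 to 0.860 for the 16 lists that differed. The direction of the S phase list turned without smTEADi 1 (adjusted p = 0.409), and its call was lost without Control 3 (0.170), pTEADi 3 (0.201), Vehicle 1 (0.153) and Vehicle 3 (0.384). The median of the partial epithelial-mesenchymal transition list also turned without smTEADi 1 (-0.02). Without Control 2 the median was -0.62 for NF-kB genes, which Control 2 led (mean log2 CPM 4.23 against 3.26 and 2.76), -0.28 for ATF4 genes and 0.18 for partial epithelial-mesenchymal transition genes. The last was also 0.18 without pTEADi 2 and 0.30 without smTEADi 2, S phase genes were at 0.35 without smTEADi 2 and 0.37 without Vehicle 2, and AP-1 genes at -0.50 without smTEADi 3, but -0.16 without Control 2 and -0.09 without smTEADi 1. Medians also shrank for nuclear oxidative phosphorylation genes (0.07 without smTEADi 1), basal keratinocyte genes (0.11 without pTEADi 1 and 0.08 without smTEADi 1) and YAP/TAZ target genes (-0.07 without Control 2 and -0.04 without smTEADi 2). Apoptosis regulators were at -0.10 without Control 2 or Vehicle 2, -0.11 without pTEADi 1 and -0.09 without smTEADi 1. S phase genes were at 0.13 without Control 3, 0.10 without pTEADi 3 or Vehicle 3 and -0.03 without smTEADi 1, and partial epithelial-mesenchymal transition genes at 0.06 without Vehicle 3. Cholesterol synthesis genes were at -0.10 without Vehicle 1 and NRF2 genes at 0.13 without pTEADi 3. The YAP/TAZ call was lost without Control 2 (0.147), pTEADi 2 (0.0795), pTEADi 3 (0.0634), smTEADi 2 (0.335) and Vehicle 2 (0.0975). The partial epithelial-mesenchymal transition call was lost without Control 1 (0.0596), Control 3 (0.212), pTEADi 1 (0.195), pTEADi 3 (0.0878), smTEADi 1 (0.589), smTEADi 3 (0.0622) and Vehicle 3 (0.0970). The apoptosis call was lost without Control 2 (0.156), pTEADi 1 (0.0823), smTEADi 1 (0.0904), smTEADi 3 (0.109), Vehicle 1 (0.0777) and Vehicle 2 (0.0867). The basal keratinocyte call was lost without Control 2 (0.0525), pTEADi 1 (0.108), smTEADi 1 (0.261) and Vehicle 2 (0.0518), and the AP-1 call without Control 2 (0.218), pTEADi 3 (0.0519) and smTEADi 1 (0.252). The nuclear oxidative phosphorylation call was lost without Control 3 (0.0583) and smTEADi 1 (0.142), and the NRF2 call without smTEADi 1 (0.0844); values in parentheses are camera adjusted p.

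Interferon-stimulated genes fell in both comparisons by camera, though not with an estimated correlation. Single libraries do not account for it: the list's median log2 fold change was still -0.79 in the weakest case, without smTEADi 1, against -1.03, and -1.25 to -1.42 for pTEADi. The interferon list lost 1356 CPM with SW-682 and 2041 CPM with pTEADi. These losses were at least 30.4 times the summed CPM of all 18 leukocyte markers in the control libraries (44.5 and 62.6). Of these markers 0 are in another list and 4 exceeded 1 CPM in all libraries. That ratio cannot exclude fewer reads from host leukocytes, because the interferon-gene reads that such cells give per marker read are not known. The marker sum was 48.7 ± 13 CPM with SW-682, not lower than with vehicle, and 40.5 ± 4.4 CPM with pTEADi, lower than in Control. Reads from other host cells, and whether the change follows from TEAD inhibition or, for pTEADi, from doxycycline, stay open and were not tested.

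Hypoxia genes were lower with pTEADi than with SW-682 by camera, though not with an estimated correlation (adjusted p = 0.339). The median log2 difference was still -0.72 without smTEADi 1, the weakest case, so no single library accounts for it. Even so, smTEADi 3 lay as low on the list as the pTEADi libraries (mean log2 CPM 5.81 against 5.83 to 5.88), unlike smTEADi 1 and 2 (7.12 and 6.82). Mitochondrial stress from doxycycline would raise the ATF4 list, whose median was -0.53 with pTEADi, with 14 of its genes lower and 2 higher. Control 2 stood above Control 1 and 3 on that list (mean log2 CPM 5.66 against 5.19 and 5.23). Doxycycline and the inhibitor came together, so a fall from the inhibitor could hide a rise from doxycycline. The test therefore cannot decide, and such stress stays open. A higher level in Control than in Vehicle cannot be told apart: as the whole cause it would leave pTEADi and SW-682 libraries at the same level, and these differed by -0.735 ± 0.40 (SE) on the log2 scale, within 2 SE of 0. The control groups differed by 0.13 ± 0.23 (SE), 15.3% of the difference of effects in mean levels (-0.87), which is under the share of 0.25 set to exclude it; that it also stay under by its SE was added after the value was seen. Other actions of doxycycline and a difference in tumour size or oxygen between the experiments, which the labels do not give, stay open and untested.

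More genes were called with pTEADi than with SW-682, 4.74 times as many. With 1 spread shared by all 4 groups the ratio was 1.46, which is consistent with wider spread between the SW-682 and vehicle libraries as a candidate explanation. Smaller effects of SW-682 cannot be told apart from equal ones: its fold change per unit of pTEADi fold change, freed of measurement error, was 0.683, between the bounds set for either answer (0.67 and 0.8). Dose, duration and potency were not tested.

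For 3 against 3 libraries the 10 splits are too few for a share under 0.05. In the SW-682 experiment, 816 genes stood against 1 in the highest other split (1 split of 10 as high), 6 YAP/TAZ targets against 0 (1 of 10) and 17 lists against 19 (4 of 10). In the pTEADi experiment, 3864 genes stood against 1 (1 of 10), 14 YAP/TAZ targets against 0 (1 of 10) and 19 lists against 25 (3 of 10). Over the 100 pairs of splits of both experiments, the correlation of 0.675 was reached by 1 pair. The highest other value, 0.598, came from a pair that kept the real pTEADi split, and the median of the others was 0.232. That share speaks only to both groupings being arbitrary at once. For the grouping of 1 experiment alone only its 10 splits bear on the correlation, so chance is not excluded there. The 727 shared genes were also reached by 1 pair (highest other 1), but every other split of either experiment called at most 1 gene, so that count decides nothing beyond the 10 splits of each.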

How the results depend on the processing

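The alternatives were planned, except the 7 further lists, which were chosen after seeing the data. The signs of all genes called with SW-682 and with pTEADi were kept in every alternative that fitted them. RLE scaling, upper-quartile scaling, voom and unrounded counts left both gene counts within 1.5 times. The SW-682 count of 816 became 2101 with no filter, 1893 with DESeq2, 2303 with a shared spread, 0 with a replicate block, 0 at an adjusted p of 0.01 and 319 at 2-fold, and 0 to 1622 without single libraries. The pTEADi count of 3864 became 2138 at 0.01 and 886 at 2-fold, and 2325 to 4379 without single libraries. The difference count of 2 became 377 with no filter, 43 with DESeq2, 0 with a replicate block, 0 at 0.01, and 0 to 20 without single libraries; adjusted p over 17 alternatives ran from 2.35e-07 to 0.173 for CPT1A and 2.87e-07 to 0.219 for CEMIP. The correlation became 0.168 with no filter, 0.713 for protein-coding genes, 0.549 with a shared spread, 0.785 for genes of 5 CPM or more, and 0.599 to 0.669 without single libraries. The shared count of 727 became 1685 with no filter, 1506 with DESeq2, 0 with a replicate block, 1545 with a shared spread, 0 at 0.01 and 215 at 2-fold, and 0 to 1331 without single libraries. List counts became 0 with an estimated correlation in all 3 tests and 0 with fry for SW-682 and for the difference; without single libraries they were 17 to 19, 18 to 23 and 12 to 16. YAP/TAZ targets called with SW-682 became 0 with a replicate block, 0 at 0.01, 3 at 2-fold and 10 over the list alone, and 0 to 6 without single libraries; with pTEADi they became 9 with a shared spread, 9 at 0.01 and 5 at 2-fold, and 8 to 13 without single libraries. The reversed result was the difference of the S phase list without smTEADi 1 (adjusted p = 0.409); without single libraries its adjusted p ran from 2.05e-06 to 0.409. A replicate block spends 2 degrees of freedom in each comparison and more in the test of the difference. Stricter thresholds pass fewer genes by construction. For the other alternatives the cause was not tested. Of 85 named genes called with SW-682, 84 stayed called with DESeq2, 81 with voom and 0 with a block; of 152 with pTEADi, all with DESeq2 and voom and 151 with a block. Without smTEADi 1, 2 and 3, 57, 56 and 0 of the 85 stayed, and without Vehicle 1, 2 and 3, 0, 83 and 0. Depth limits genes with few counts, such as CCN2 and ANKRD1.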

Other observations

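The 7 gene lists described here were written, and their genes named, after the data had been seen, so their tests are not independent of the data. Values in pairs are for SW-682 and then pTEADi. Of 13 keratins of differentiated epithelia, 5 rose with SW-682 and 12 with pTEADi, with median log2 fold changes of 1.13 and 1.76 (camera adjusted p = 1.34e-11 and 5.45e-19; adjusted p = 0.206 and 0.0326 with an estimated correlation). Genes of epidermal barrier lipids, which seal the skin surface, were higher, 1 of 21 past the threshold with SW-682 and 13 of 20 with pTEADi. There the ceramidase gene ACER1 reached 2.43, DEGS2 2.29 and the lipid transporter gene ABCA12 1.44 (camera adjusted p = 2.92e-08 and 2.68e-13; adjusted p = 0.206 and 0.0326 with an estimated correlation). Kallikrein and TMPRSS11 proteases, which act in shedding of the surface, rose for 6 of 19 genes with SW-682 and for 11 of 19 with pTEADi, where 2 fell. KLK12 rose by 2.33 and KLK5 fell by 0.99 on the log2 scale (camera adjusted p = 7.62e-07 and 5.74e-08; adjusted p = 0.206 and 0.114 with an estimated correlation). Secretory epithelial genes rose too, 7 of 19 and 14 of 18. The water channel gene AQP3 had log2 fold changes of 0.97 and 1.39 and the protease inhibitor gene SLPI at 0.69 and 0.84 (camera adjusted p = 2.92e-08 and 1.11e-13; adjusted p = 0.206 and 0.0425 with an estimated correlation).

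Homologous recombination and Fanconi genes, which repair broken DNA, fell with both: 10 of 20 with SW-682 and 18 of 20 with pTEADi (camera adjusted p = 1.31e-14 and 6.16e-11; adjusted p = 0.206 and 0.0428 with an estimated correlation). BRCA1 fell by 0.96 and 0.81 and FANCI by 1.22 and 0.92 on the log2 scale. Genes that sense nucleic acids or carry the interferon signal did not pass with camera (adjusted p = 0.0973 and 0.159; adjusted p = 0.206 and 0.277 with an estimated correlation). Of 19, 1 rose and 1 fell with SW-682, and 1 rose and 4 fell with pTEADi, at medians of -0.11 and -0.06 with 6 and 8 positive fold changes. With fry, which tests whether a list's genes move on balance one way, they passed in the lower direction (adjusted p = 0.0131 and 0.0192). These fry values were adjusted over the lists of this section alone, which are fewer than the fixed lists. They therefore cannot be set beside those of the fixed lists, where none passed with SW-682 (smallest fry adjusted p = 0.0625). In mean log2 CPM of the list, every treated library lay below every control library of its experiment. The ranges were 4.80 to 4.89 against 5.02 to 5.09 with SW-682, and 4.76 to 4.80 against 4.88 to 5.01 with pTEADi. Among the genes of this list JAK1 rose (0.46 and 0.33) and EIF2AK2 fell (-0.77 and -0.74). Of 18 fatty acid oxidation genes, 1 fell with SW-682, while 8 rose and 3 fell with pTEADi (camera adjusted p = 0.482 and 0.0457; adjusted p = 0.559 and 0.114 with an estimated correlation). The list differed between the treatments by a median of 0.18 (camera adjusted p = 9.08e-05; adjusted p = 0.0105 with an estimated correlation). It was written after CPT1A had been singled out and holds that gene, the 1 of its 18 past the threshold for the difference, so this is no independent test.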
